A study of Mus musculus with 2 samples.

How the data were processed

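The data are 2 RNA-seq libraries of mouse small intestine, with a gene table and a transcript table for each. Per the labels, RNA above 200 nt was poly(A)-selected and depleted of ribosomal RNA, and stranded paired reads of 76 nt were sequenced on an Illumina GAIIx, with spike-in RNA added. The labels number the libraries as biological replicates 1 and 2 from separate biosamples of C57BL/6J mice under a shared strain-level donor entry, and give no other grouping. The deposited text beside the tables names the mm10 assembly and annotation release M4. The aligner and the quantifier are not given in the sources used here, though the column names of the tables are those RSEM writes.

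Each deposited table gives expected counts, that is, estimated fragments per feature that need not be whole. The authors' TPM values (transcripts scaled to 1 fixed total per library) run over all features of a table, spike-ins included, and the deposited FPKM values are fragments scaled by length and library total. The deposited transcript tables give the percent of each gene's TPM that comes from each transcript. Lower and upper bounds of a credibility interval and posterior mean TPM are also deposited; the level of the interval is not stated in the file. TPM divides by effective length, which shrinks with the mean fragment length. That mean was 237 nt in replicate 1 and 219 nt in replicate 2, so features of about 200 nt have an effective length near 0 and their TPM does not measure their level.

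The gene tables hold 69691 features, of which 43346 are Ensembl genes, 26248 have numeric names and no counts in either library, 96 are spike-ins and 1 is phiX, also without counts. Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, which is the assembly named mm10, by the stable part of the gene identifier. This matched 42462 genes (98.0%), 23106 of them in the same version, and the unmatched genes held 0.0447% and 0.0946% of TPM. Totals were 45472946 and 45822403 expected counts. The share of spike-in counts carries a 95% exact (Clopper-Pearson) binomial interval, and 3 counts were taken as the upper limit that a count of 0 allows.

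A gene was called detected at a TPM of at least 1 in both libraries. Correlations across genes used log2(TPM + 1). The common dispersion was estimated with edgeR 4.0.16 (R 4.3.3) on expected counts rounded to whole numbers, with TMM factors, an intercept-only design and the tool's default filter on low counts, and its square root is the biological coefficient of variation. DESeq2 1.42.0 served as the alternative. Replicate ratios are log2((TPM + 1) / (TPM + 1)), replicate 2 over replicate 1, for genes with mean TPM of at least 10 and a threshold of 2-fold; the pseudocount understates the ratio of low genes. For 48 gene lists (cell types, pathways, segments, neighbouring tissues and RNA classes) the summed TPM, the median member and the number detected were taken, and for the 39 lists with at least 5 members of mean TPM of at least 1 the median log2 ratio minus that of all genes with mean TPM of at least 1 was placed among 10000 random lists of the same size drawn from the same deciles of mean TPM. A list stood outside when its percentile was under 2.5 or over 97.5. A rounded-count chi-square test over genes compared the libraries themselves. Other values came from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

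The lists, the measures and the rule for named genes were fixed before the data were examined. The rule allows the 20 genes with the highest mean TPM; for each list the 4 members with the highest mean TPM and its members under 1 TPM in both libraries where these are 5 or fewer; any member of the segment, Paneth, goblet, enteroendocrine, sex-linked and neighbouring-tissue lists; the 12 highest and 12 lowest replicate ratios with separate credibility intervals; and, by major isoform share (that of the transcript with the highest mean share over both libraries), 8 genes with the lowest share and 5 with the widest gap. Genes named outside this rule are said to be so.

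The steps were tested on simulated data. For replicate 2 against replicate 1 over 15001 genes with 200 changed 4-fold, a simulated coefficient of variation of 0.2 was recovered as 0.229 and one of 0.4 as 0.404. Of 200 unshifted random lists over 12260 genes, 9 (4.5%) fell outside the central range, and of 200 lists shifted by 1 log2 unit all 200 did. The simulated ratios were independent between genes, so this does not cover lists whose genes vary together. For the 2-fold count, centred on the median gene over 5926 genes, a simulated coefficient of variation of 0.15 gave 200 of 200 genes changed 4-fold, with 2 unchanged genes. At 0.4 it gave 170 of the 200 (85.0%), with 1285 unchanged genes (22.4%). The value of 0.4 is near the common coefficient of these libraries, 0.413, but above the 0.165 from the median gene's dispersion in DESeq2.

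Alternatives were other pseudocounts, TPM minimums, FPKM, posterior mean TPM, expected counts, TMM and DESeq2 scaling, centring on the median gene, Spearman's rho, no filter on low counts, medians in place of sums, lists without their most abundant member, leaving out mitochondrial genes, and leaving out each replicate. Added after the values were seen were spike-in scaling, TPM rescaled without the exocrine pancreas and stomach lists, and shorter segment and Paneth lists.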

Results

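Poly(A)-selected RNA from the small intestine of adult C57BL/6J mice aged 8 weeks was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. C57BL/6J is a widely used inbred strain. The labels give RNA above 200 nt, depleted of ribosomal RNA, read from both ends in reads of 76 nt with the strand kept, and describe the tissue as pooled from male and female animals. They name no segment of the intestine and no treatment, so the design asks what RNA this tissue holds and how far its 2 replicates differ. Replicate 1 held 45472946 expected counts and replicate 2 held 45822403. At this depth a count of 0 allows a share of up to 6.60e-06% in replicate 1 and 6.55e-06% in replicate 2, taken as 3 counts of the total. Intervals and floors cover counting error only. With 1 group of n = 2 no test between groups was made, and the values below are each replicate's own or the mean ± SD of both.

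By TPM, the most abundant transcripts came from epithelial, immune and pancreatic genes and from short structural RNA. The highest mean level belonged to Sprr2a2, a small proline-rich protein gene (ENSMUSG00000068893.5, chromosome 3, 92215920 to 92256724, GRCm38), at 36141 ± 10468 TPM (SD, n = 2), with 43542 and 28739 TPM in replicates 1 and 2. It ranked first in neither library, since Ctrb1 and Cela2a were higher in replicate 1 and Igkc in replicate 2. The annotated span of Sprr2a2 overlaps that of its near copy Sprr2a1, a gene outside the naming rule, so the split of reads between them is uncertain. Igkc, the constant region of the immunoglobulin kappa light chain, held 23138 TPM in replicate 1 and 41938 TPM in replicate 2, and Igha, the constant region of the IgA heavy chain, held 8008 and 20453 TPM. Crip1, a cysteine-rich protein of the intestine, was listed at 4954 and 16824 TPM, Apoa1, the main protein of high-density lipoprotein, at 2549 and 13042 TPM, and Actb, the cytoskeletal beta-actin, at 3775 and 9786 TPM. Of the 20 genes with the highest mean, 9 encode pancreatic products (Ctrb1, Cela2a, Clps, Prss2, Try4, Cela1, Cela3b, Ctrl and Sycn), and all of these had the higher value in replicate 1. The short structural RNAs Rn7s1 and Rn7s2, which share their sequence and so cannot be separated by reads, were each listed at 27899 and 6965 TPM, Rn7sk at 15536 and 18090 TPM, and Rmrp at 14328 and 2935 TPM. The credibility intervals of Rn7s2 overlapped between the libraries. Such short RNAs rank far lower by counts. In replicate 1 the annotation class that holds Rn7s1, Rn7s2 and Rn7sk took 7.15% of TPM but 0.568% of counts, and that of Rmrp 1.92% and 0.102%. Gm42418, which the annotation classes as a long noncoding RNA, was listed at 41259 and 22178 TPM. Which RNA its reads come from was not examined.

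A total of 11193 genes had a TPM of at least 1 in both replicates, of which 10597 (94.7%) were protein-coding. Replicate 1 had 11580 such genes and replicate 2 had 12528. The 100 most abundant genes took 67.3% of all TPM in replicate 1 and 43.7% in replicate 2 (55.5% ± 16.6, SD, n = 2). A TPM minimum of 5 left 6815 genes.

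Across genes, log2(TPM + 1) in the replicates correlated with Pearson's r = 0.960 and Spearman's rho = 0.946; genes are not independent replicates, so no p is given. The median gene with mean TPM of at least 1 (12260 genes) lay 0.66 log2 units higher in replicate 2. With TPM rescaled without the exocrine pancreas and stomach lists, chosen after the values were seen, it lay 0.27 higher. On the TPM scale the spike-in RNAs lay 0.31 log2 units higher in replicate 2 (1.21% and 1.51% of TPM), whereas their share of counts was lower there, so spike-in scaling below rests on the TPM scale. Differences of gene lists are given relative to the median gene. Credibility intervals of the replicates, which are not centred in this way, overlapped in only 522 of the 5926 genes with mean TPM of at least 10. Intervals apart are therefore usual and do not by themselves mark a list. The biological coefficient of variation, the spread between replicates beyond counting noise, was 0.413 over 15001 genes, and the square root of the median gene's dispersion in DESeq2 was 0.165. Counts of the libraries differed by more than counting noise (chi-square test, 1193 per degree of freedom over 17052 degrees of freedom), which does not show whether they are separate biological samples. Spike-in RNAs took 1.05% of counts in replicate 1 (95% exact interval 1.049% to 1.055%) and 1.03% in replicate 2 (1.026% to 1.032%).

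**Figure D1:**
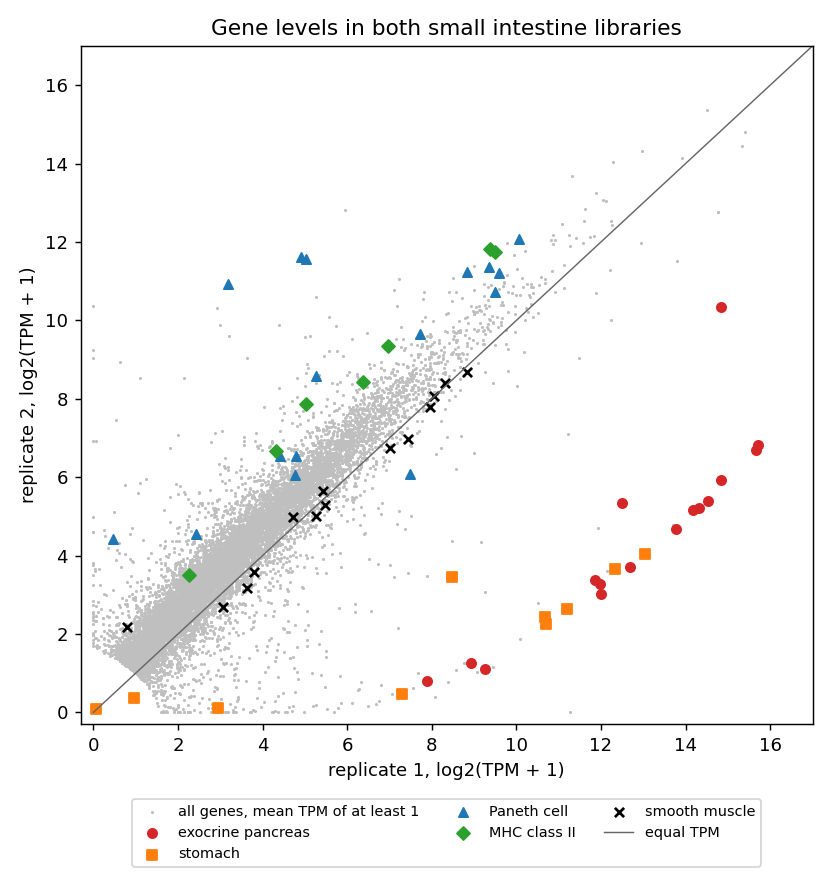
Each point is a gene with mean TPM of at least 1, or a member of the named list, placed by log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis); the line marks equal TPM. All 16 exocrine pancreas genes lie far below the line, while the 7 MHC class II genes lie above it.

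Pancreatic and stomach transcripts separated the replicates most. The 16 genes of the exocrine pancreas list, which encode digestive zymogens and enzymes, summed to 266063 TPM (26.6% of all TPM) in replicate 1 and to 1778 TPM (0.178%) in replicate 2. Ctrb1, chymotrypsinogen (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010, GRCm38), held 53239 TPM in replicate 1 and 112 TPM in replicate 2. Cela2a, an elastase (ENSMUSG00000058579.5, chromosome 4, 141814962 to 141826160), held 52189 and 102 TPM, and Prss2, a trypsinogen, held 29354 and 60.3 TPM. Clps, the cofactor of pancreatic lipase, differed less, at 29051 and 1288 TPM, and so did Rnase1, a secreted ribonuclease, at 5765 and 39.4 TPM. All 16 members had credibility intervals apart between the libraries, with replicate 1 above. The list's median lay at -9.56 log2 units relative to the median gene, below every one of 10000 random lists of the same size matched on mean TPM. In the endocrine pancreas list, Ins2, an insulin gene, was at 76.7 and 0.51 TPM, Ins1 at 13.1 and 0.03 TPM, Ppy, the pancreatic polypeptide gene, at 9.18 and 0 TPM, and Iapp, the islet amyloid gene, at 1.66 and 1.47 TPM.

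The stomach list of 10 genes summed to 19753 TPM in replicate 1 and 51.5 TPM in replicate 2. The trefoil factor Tff2 was at 8479 and 15.6 TPM, its relative Tff1 at 5130 and 11.6 TPM, the gastrokines Gkn3, Gkn2 and Gkn1 at 2342, 1652 and 1630 TPM in replicate 1 and at 5.23, 3.81 and 4.38 TPM in replicate 2, and the gastric mucin Muc5ac at 157 and 0.39 TPM. Pgc, pepsinogen C, was at 355 and 10.04 TPM, and Gif, intrinsic factor, at 6.74 and 0.08 TPM. The proton pump genes of acid-secreting cells, Atp4a and Atp4b, stayed under 1 TPM in both (0.95 and 0.30 TPM, and 0.05 and 0.07 TPM). The median of the 8 members with mean TPM of at least 1 was -9.00 log2 units relative to the median gene, below every random list. The liver list of 10 genes summed to 5.43 and 4.36 TPM, with Alb, serum albumin, at 0.24 and 0 TPM, the colon list of 9 to 23.2 and 20.3 TPM, mostly from the chloride exchanger Slc26a3 (16.51 and 15.2 TPM), and the skeletal muscle list of 8 to 28.3 and 28.0 TPM. The red blood cell list summed to 183 and 192 TPM. The adipocyte list summed to 198 and 319 TPM, most of it from the lipid droplet gene Cidec (125 and 283 TPM), while its median over 6 members lay at -1.19 log2 units relative to the median gene, with the hormone gene Adipoq at 2.01 and 0.83 TPM.

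Genes of the small intestine's segments were also unevenly held. Among the 13 genes of the proximal list, 7 had log2 ratios under -1 and only Lct, the lactase gene, had a ratio over 1. Pdx1, a transcription factor of duodenum and pancreas (ENSMUSG00000029644.6, chromosome 5, 147269959 to 147275848), was at 25.3 TPM in replicate 1 and 0.12 TPM in replicate 2. The iron exporter Slc40a1 was at 27.1 and 1.04 TPM, the iron reductase gene Cybrd1 at 16.5 and 1.24 TPM, the iron transporter Slc11a2 at 111 and 32.3 TPM, Onecut2 at 4.42 and 0.74 TPM, the hormone gene Ghrl at 37.8 and 10.7 TPM, and Ada, adenosine deaminase, at 697 and 339 TPM. Gata4 stood at 95.5 and 104 TPM, Fabp1 at 80.4 and 96.5 TPM, Rbp2 at 273 and 483 TPM, Gip at 20.4 and 36.4 TPM, Lct at 55.5 and 341 TPM, and Hephl1 at 0 and 0.03 TPM. The proximal median was -2.00 log2 units relative to the median gene, below every random list, although the list summed to 1444 and 1446 TPM. Any part of these values that came with the pancreas and stomach RNA of replicate 1 was not separated from that of the intestine.

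In the distal list of 12 genes, 11 had credibility intervals apart with replicate 2 above and 1 (Ces1f, a carboxylesterase, 32.7 and 3.69 TPM) with replicate 1 above. Intervals apart are usual in these libraries, as given above, and are not centred on the median gene. On the log2(TPM + 1) scale the receptor complex for vitamin B12 showed the widest gaps of this list, with Cubn (ENSMUSG00000026726.10, chromosome 2, 13276338 to 13491813) at 0.20 and 24.3 TPM and its partner Amn at 87.5 and 820 TPM. As plain ratios of TPM, Fabp6, Nts and Slc10a2 exceeded Amn. The peptide hormone gene Pyy was at 110 and 488 TPM, Nts at 0.19 and 7.15 TPM, the bile acid exporter subunits Slc51a and Slc51b at 73.1 and 300 TPM and at 4.68 and 8.36 TPM, and Tcn2, a carrier of vitamin B12, at 150 and 370 TPM. Genes most typical of the ileum were low in both: the bile acid importer Slc10a2 at 0.13 and 1.85 TPM, the bile acid binding protein gene Fabp6 at 0.08 and 4.95 TPM, and the hormone gene Fgf15 at 0 and 1.52 TPM (0 and 95 counts). The bile acid receptor gene Gpbar1 was at 1.43 and 2.52 TPM. The distal median lay 1.42 log2 units above the median gene, above every random list. The log2 ratio of summed distal to summed proximal TPM was -1.65 in replicate 1 and 0.49 in replicate 2 (-0.58 ± 1.51, SD, n = 2), so the mean did not exceed the spread between replicates, and without replicate 1 its sign was reversed. The sign in replicate 2 depended on the measure, since as a difference of medians the values were -3.38 and -1.93 (-2.66 ± 1.03, SD, n = 2). Without Fabp1, Lct, Rbp2 and Ada, an alternative chosen after the values were seen, the ratios were 0.45 and 3.44.

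**Figure D2:**
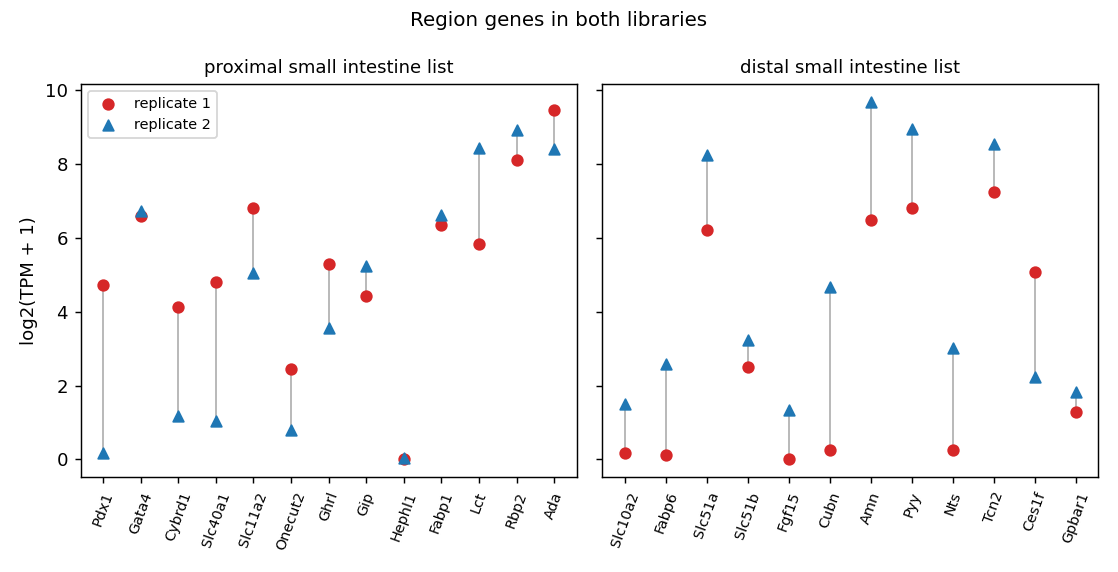
Points give log2(TPM + 1) of each gene of the proximal list (left) and the distal list (right) in replicate 1 (circles) and replicate 2 (triangles), with a line joining the replicates. Pdx1, Cybrd1 and Slc40a1 are higher in replicate 1, and Cubn, Amn and Pyy are higher in replicate 2.

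Absorptive cell genes took a larger share of replicate 2. The 18 brush border genes summed to 6477 TPM in replicate 1 and 11047 TPM in replicate 2 (8762 ± 3231, SD, n = 2). Of these, 17 had intervals apart with replicate 2 above, though intervals apart are usual here. The aminopeptidase Anpep was at 512 and 2687 TPM and the brush border cadherins Cdhr5 and Cdhr2 at 398 and 1011 TPM and at 379 and 820 TPM. Alpi, intestinal alkaline phosphatase, went the other way, at 3759 and 1663 TPM. The list median was 1.42 log2 units above the median gene, above every random list. The 14 genes of sugar, peptide and amino acid uptake summed to 1226 and 3300 TPM, with a median 1.00 above the median gene at percentile 99.99 of random lists. The neutral amino acid transporter Slc6a19 was at 196 and 752 TPM, the sodium-glucose cotransporter Slc5a1 at 227 and 512 TPM, the ketohexokinase gene Khk at 228 and 468 TPM and the cystine transporter subunit Slc7a9 at 97.6 and 262 TPM, while Slc6a14 was at 0.01 and 0 TPM.

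The 18 genes of fat and sterol absorption summed to 7097 and 26040 TPM, with a median 0.86 above the median gene at percentile 99.97. Apolipoprotein genes led the list, with Apoa4 at 1916 and 4255 TPM and Apoc3 at 880 and 3990 TPM, followed by the triglyceride synthesis gene Dgat1 at 638 and 1831 TPM. With TMM-scaled counts in place of TPM, this list fell inside the random range, at percentile 96.4. The 19 intestinal transcription factor genes had a median 0.62 above the median gene at percentile 99.85, with Klf4 at 142 and 479 TPM, Creb3l3 at 131 and 406 TPM, Klf5 at 127 and 378 TPM and Hnf4a at 143 and 325 TPM. Both libraries had all 19 at or above 1 TPM.

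Paneth cell genes, which encode the antimicrobial peptides of the crypt base, summed to 4231 TPM in replicate 1 and 23088 TPM in replicate 2 (13659 ± 13334, SD, n = 2). Lysozyme Lyz1 was at 650 and 2627 TPM, Itln1, an intelectin, at 454 and 2416 TPM, Ang4 at 37.5 and 381 TPM, and Mmp7, the protease that activates defensins, at 26.6 and 91.6 TPM. Among the alpha-defensin genes, Defa24 was at 1062 and 4303 TPM, Defa3 at 770 and 2367 TPM, Defa23 at 722 and 1698 TPM and Defa30 at 209 and 801 TPM. Larger gaps were listed for Defa22 at 28.9 and 3130 TPM, Defa21 at 31.8 and 3055 TPM and Defa20 at 8.04 and 1950 TPM. Defa17 was at 20.4 and 92.1 TPM, Defa26 at 4.39 and 22.4 TPM, Defa5 at 0.39 and 20.6 TPM and Mptx2 at 26.01 and 65.1 TPM. The Defa genes are near-identical copies whose reads the quantifier had to divide, so the value of each copy is uncertain. Pnliprp2, a lipase also made by the pancreas, went the other way at 179 and 66.6 TPM. The list median was 1.40 above the median gene, above every random list.

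Goblet cell genes, which encode mucus proteins, summed to 14534 and 24671 TPM, and their median of 0.26 above the median gene was at percentile 56.1, inside the random range. Tff3 was at 4211 and 8642 TPM, Spink4 at 3124 and 5917 TPM, Zg16 at 3074 and 4010 TPM, Fcgbp at 988 and 3232 TPM, the mucin Muc2 at 363 and 2153 TPM, Clca1 at 110 and 260 TPM, Agr2 at 221 and 206 TPM and Spdef at 35.4 and 41.7 TPM. Klk1, a kallikrein also made by the pancreas, was at 2380 and 136 TPM. Retnlb was at 0.81 and 0 TPM. The log2 ratio of summed Paneth to summed goblet TPM was -1.78 in replicate 1 and -0.10 in replicate 2 (-0.94 ± 1.19, SD, n = 2), so the mean did not exceed the spread between replicates. The sign in replicate 2 depended on the measure: as a difference of medians the values were -3.002 and 2.33, and without the most abundant member of each list -1.70 and 0.23. Without the Defa genes, chosen after the values were seen, the mean ratio was -2.77.

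The regenerating-protein lectins, antimicrobial and growth-related proteins of gut and pancreas, went the other way, with 5 of 7 genes over 2-fold higher in replicate 1 on the TPM scale. Reg1 was at 3905 and 25.1 TPM, Reg2 at 696 and 1.23 TPM, Reg3b at 2837 and 525 TPM and Reg3g at 1037 and 322 TPM. The median lay at -3.09 log2 units, at percentile 0.01.

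Hormone genes of enteroendocrine cells summed to 809 and 1580 TPM, with a median 0.12 above the median gene (percentile 77.5). Secretin, Sct, was at 259 and 570 TPM, somatostatin, Sst, at 142 and 244 TPM, Cck at 201 and 138 TPM, the granule protein gene Chga at 19.5 and 46.8 TPM, Gcg at 2.44 and 15.6 TPM and Tac1 at 1.48 and 3.08 TPM. Neurod1 (0.72 and 2.09 TPM), Pax4 (0.43 and 0.33 TPM) and Nts were under 1 TPM in at least 1 library. The tuft cell list summed to 86.6 and 104 TPM, with Ptgs1 at 23.3 and 26.7 TPM and Alox5ap at 22.6 and 13.2 TPM, and its median of -0.39 was inside the random range (percentile 5.46), but outside it over members with mean TPM of at least 5 (-0.48, percentile 2.26). Crypt stem cell genes summed to 237 and 315 TPM, with Olfm4 at 76.04 and 80.0 TPM and Ephb2 at 25.9 and 47.5 TPM, and a median of -0.24 (percentile 3.23). The proliferation list summed to 123 and 249 TPM, with Ube2c at 31.4 and 74.7 TPM and Pcna at 26.1 and 44.97 TPM, and a median of 0.25 (percentile 95.6).

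Immune genes differed by class. The 7 MHC class II genes, which present antigen, were all over 2-fold higher in replicate 2 on the TPM scale and summed to 1644 and 8348 TPM. H2-Ab1 was at 662 and 3616 TPM, the invariant chain Cd74 at 722 and 3399 TPM, H2-Aa at 124 and 646 TPM and H2-Eb1 at 82.1 and 344 TPM. The median was 1.68 above the median gene, above every random list. The 14 interferon response genes summed to 247 and 902 TPM, with a median of 1.01, again above every random list. The regulator Irf7 was at 73.9 and 398 TPM, Bst2 at 87.8 and 191 TPM and Isg15 at 22.6 and 73.9 TPM. Plasma cell genes took 3.22% of TPM in replicate 1 and 6.41% in replicate 2, with Jchain, the joining chain of IgA, at 814 and 1413 TPM and the secretory regulator Xbp1 at 63.5 and 102 TPM. Their median of 0.15 was at percentile 56.1.

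The T cell and intraepithelial lymphocyte list summed to 960 and 807 TPM, most of it the chemokine Ccl5 (867 and 678 TPM), with Cd7 at 32.9 and 47.3 TPM, Cd3e at 10.4 and 11.04 TPM and Gzmb at 9.03 and 10.2 TPM. Its median of -0.36 was at percentile 2.34, and it was inside the random range with a pseudocount of 0.1 (percentile 7.52) and with TMM scaling (percentile 7.13). The B cell and follicle list summed to 49.8 and 101 TPM with Cd79a at 18.6 and 44.5 TPM, and its median of 0.15 was at percentile 94.7, or 99.1 with TMM scaling. Macrophage and dendritic cell genes summed to 279 and 308 TPM, led by C1qc (66.2 and 88.5 TPM) and Lyz2 (85.4 and 60.0 TPM), with a median of -0.55 at percentile 0.18. Granulocyte and mast cell genes summed to 10.4 and 16.1 TPM. In the M cell and follicle epithelium list, Gp2, a glycoprotein also made by pancreatic acinar cells, was at 203 and 1.01 TPM, and the median of 0.01 was inside the random range.

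The 14 smooth muscle genes summed to 1763 and 1642 TPM (1702 ± 85.6, SD, n = 2), with the actin Acta2 at 454 and 411 TPM, Myl9 at 315 and 338 TPM, Tagln at 264 and 266 TPM and Actg2 at 247 and 219 TPM. Their median of -0.84 relative to the median gene was below every random list. Fibroblast and matrix genes summed to 687 and 873 TPM, with Sparc at 244 and 304 TPM and Vim at 210 and 235 TPM, and a median of -0.54 (percentile 0.05). The direction of the fibroblast, macrophage, T cell and histone lists flips between scalings: on the TPM scale without centring their medians were higher in replicate 2. The same flip occurred in the tuft cell, crypt stem cell, bile acid, drug metabolism, fasting, interstitial cell of Cajal and enteric neuron lists, whose medians were inside the random range. Endothelial genes summed to 192 and 379 TPM, with Plvap at 154 and 289 TPM and Vwf at 19.8 and 52.1 TPM, and a median of 0.25 (percentile 91.9). In the mesothelium list the median was -1.64 (percentile 0.07), with Upk3b at 4.47 and 1.79 TPM and Lrrn4 at 3.24 and 0.60 TPM, although Krt19, which epithelium also expresses, was at 972 and 1888 TPM. The list of the interstitial cell of Cajal, the pacemaker cell of the gut, summed to 22.3 and 20.5 TPM with Ano1 at 13.9 and 6.90 TPM, enteric neuron genes summed to 26.4 and 36.1 TPM with Uchl1 at 8.07 and 10.5 TPM, and both medians (-0.51 and -0.33) were inside the random range. Enteric glia genes summed to 31.8 and 111 TPM, mostly from Erbb3 (25.9 and 104 TPM). The log2 ratio of smooth muscle to brush border TPM was -1.88 in replicate 1 and -2.75 in replicate 2 (-2.31 ± 0.62, SD, n = 2). The gap between the replicates was wider by other measures. As a difference of medians the values were -1.24 and -3.36, and without the most abundant member of each list -1.05 and -2.93.

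**Figure D3:**
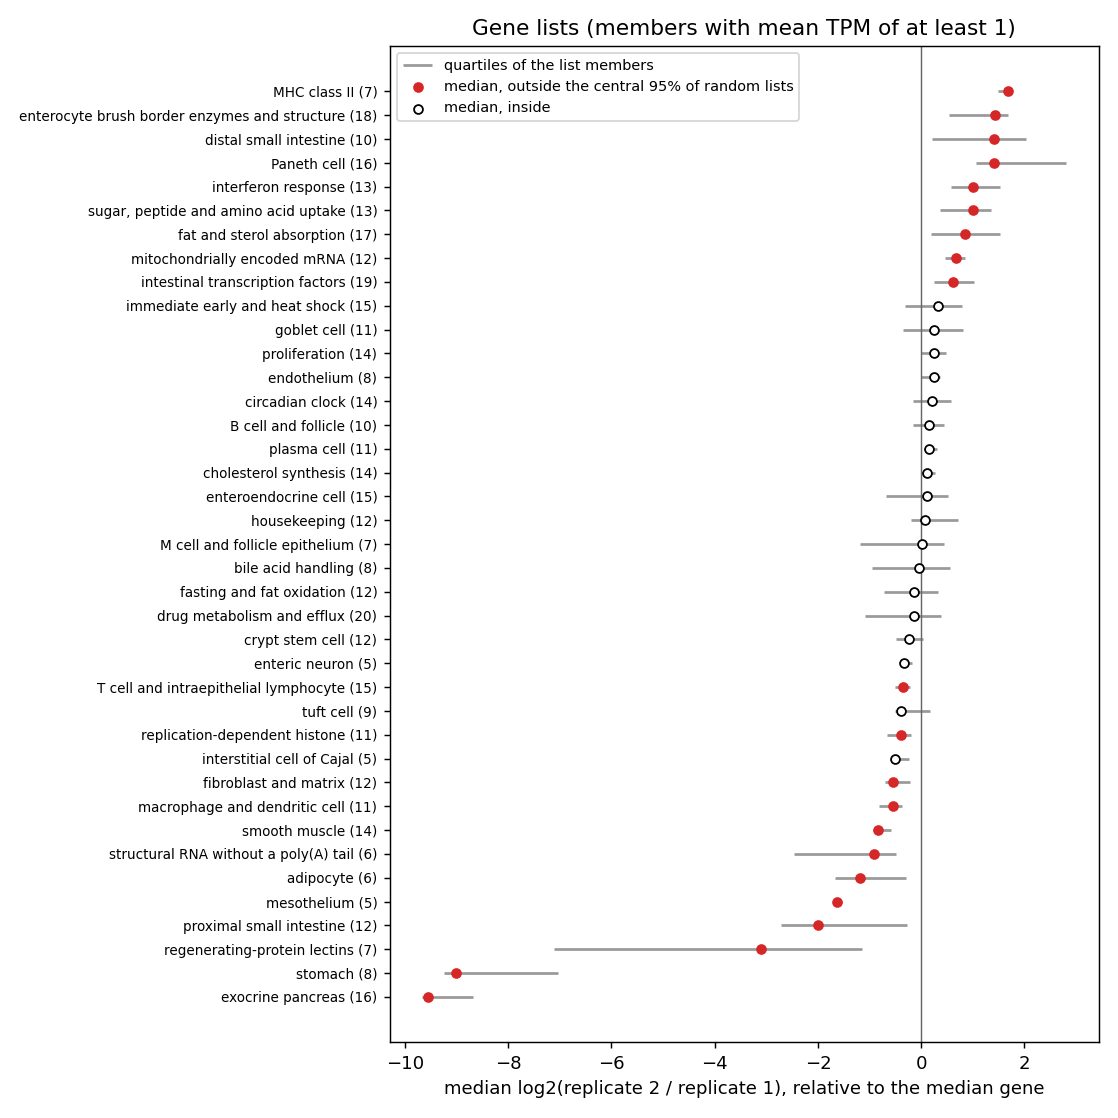
Circles give the median log2 ratio of replicate 2 to replicate 1 of each gene list minus that of the median gene, and lines span the quartiles of its members, whose number is in parentheses; filled circles mark medians outside the central 95% of 10000 random lists. Medians run from -9.56 in the exocrine pancreas list to 1.68 in the MHC class II list.

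Of the 48 lists, 39 had at least 5 members with mean TPM of at least 1. In 21 of these the median lay outside the central 95% of random lists, 12 below and 9 above. Lists of unrelated genes would give about 1.95. Genes of a list can vary together and some lists share genes, so setting 21 against 1.95 is no test. The count of 21 describes these 2 libraries, not a condition. Metabolic lists were mostly inside. Bile acid handling had a median of -0.04 (percentile 37.6), drug metabolism and efflux -0.15 (percentile 3.62), fasting and fat oxidation -0.13 (percentile 16.0), cholesterol synthesis 0.12 (percentile 54.0), the circadian clock 0.20 (percentile 93.1, or outside the range at 98.05 over members with mean TPM of at least 5), and immediate early and heat shock genes 0.32 (percentile 90.5). Abcc3 was at 150 and 34.3 TPM, Cyp4f14, a fatty acid hydroxylase, at 261 and 1018 TPM, Ces2e, a carboxylesterase, at 309 and 582 TPM, the glutathione transferase Gstm1 at 297 and 107 TPM, the clock repressor Nr1d1 at 48.0 and 168 TPM and the immediate early gene Fos at 82.8 and 232 TPM. The housekeeping list had a median of 0.08 (percentile 32.9), with Gapdh at 2252 and 2711 TPM. On the level side, 25 of the 48 lists had a median member at or above 10 TPM.

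RNA classes outside the usual coding genes differed as well. Mitochondrially encoded mRNA took 0.952% of TPM in replicate 1 and 2.16% in replicate 2 (1.56% ± 0.85, SD, n = 2), with mt-Co1 at 4451 and 8513 TPM and mt-Co3 at 3130 and 7296 TPM. Their median of 0.67 relative to the median gene was at percentile 98.8. mt-Atp8 (chromosome M, 7766 to 7969) was listed at 0 and 1321 TPM on 28 and 105 counts. It is 204 nt long, and its effective length was 0 nt in replicate 1 and 2.02 nt in replicate 2, so neither TPM measures its level. The share of mitochondrially encoded mRNA given above includes mt-Atp8, whose 1321 TPM adds to replicate 2 alone. The 11 genes of the list of structural RNA without a poly(A) tail, which does not hold Rn7s1 and Rn7s2, took 3.48% and 2.21% of TPM, with a median of -0.91 (percentile 0.22). Replication-dependent histone genes summed to 543 and 1406 TPM, led by Hist1h2bc at 321 and 1154 TPM, with a median of -0.39 (percentile 0.79, or 3.89 with TMM scaling). Long noncoding RNA genes of the list summed to 171 and 322 TPM, with Neat1 at 109 and 234 TPM and Malat1 at 22.9 and 40.0 TPM.

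Sex-linked genes split the libraries although the labels describe both sexes in each. Xist, the noncoding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had 7520 counts in replicate 1 and 35 in replicate 2 (8.88 and 0.05 TPM). The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had no count in replicate 1 and 650, 152, 100 and 50 counts in replicate 2 (3.75, 3.10, 0.88 and 0.36 TPM).

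Among the 5926 genes with mean TPM of at least 10, 2249 differed by over 2-fold on the log2(TPM + 1) scale, 2066 higher in replicate 2 and 183 higher in replicate 1, and 2232 of them had credibility intervals that did not overlap. Centred on the median gene, the count was 777, with 464 higher in replicate 2 and 313 higher in replicate 1. TMM-scaled counts gave 711, with 381 and 330. At a simulated coefficient of variation of 0.4, 1285 unchanged genes passed the threshold centred on the median gene, and at 0.15 only 2 did. The 777 genes found here are fewer than 1285, so a coefficient of 0.4 shared by all genes exceeds what these libraries show. How many of the 777 passed by replicate noise is not known, so passing the threshold does not by itself mark a gene. With scalings chosen after the values were seen, spike-in scaled TPM gave 1243 (1016 and 227), and TPM rescaled without the exocrine pancreas and stomach lists gave 1004 (741 and 263). Genes with mean TPM of at least 1 gave 3432 (3050 and 382). The 12 lowest ratios with separate intervals were all of pancreatic or gastric genes. Amy2a1, a pancreatic amylase, was at 2465 and 0 TPM, but its near-identical copies make the split of reads uncertain. Ctrc, a chymotrypsin, was at 6902 and 11.4 TPM (its annotated span overlaps Cela2a), Try5 at 6615 and 12.1 TPM, Cel at 4098 and 7.17 TPM, the trypsinogen-like 2210010C04Rik at 4193 and 7.49 TPM and Sycn, of zymogen granules, at 13409 and 26.7 TPM. Among the 12 highest were 3 annotated genes of at most 210 nt, mt-Atp8, Gm10774 and Gm10443, all with an effective length of 0 nt in replicate 1. The others were the phospholipase gene Plb1 at 0.05 and 121 TPM, the sphingomyelinase gene Enpp7 at 6.57 and 1276 TPM, Fam151a at 1.15 and 368 TPM, the transcription factor Osr2 at 0.45 and 175 TPM, the defensins Defa20, Defa32 and Defa33 (0.55 and 489 TPM for Defa32, 60.4 and 7220 TPM for Defa33), and the immunoglobulin variable genes Ighv1-12 (6.98 and 949 TPM) and Igkv1-133 (0 and 121 TPM).

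At the level of isoforms, 4318 genes with mean TPM of at least 10 had at least 2 annotated transcripts. The major transcript of a gene is here the one with the highest mean share over both libraries, so it can be a minor one in either. Its median share of a gene's TPM was 72.3% in replicate 1 and 72.4% in replicate 2, and the most abundant transcript differed between the libraries in 497 genes (11.5%). Among the list genes with the lowest mean shares of this transcript were Meg3 (22.9% ± 4.95, SD, n = 2), Irf7 (27.4% ± 11.6), Trpm5 (30.2% ± 11.8), Oasl2 (31.2% ± 10.6), Ptgs1 (34.4% ± 17.8), Gapdh (37.6% ± 21.4) and Abcc2 (41.3% ± 1.83). Among list genes the widest gaps between the libraries were in Cyp2c66, where this transcript took 9.15% in replicate 1 and 96.1% in replicate 2, the iron transporter gene Slc11a2 with 19.2% and 86.2%, Hnf4a, a transcription factor of the gut epithelium, with 21.6% and 69.6%, Tcf7l2, a Wnt pathway factor, with 27.8% and 67.2%, and Treh, the trehalase gene, with 73.8% and 35.1%. In all of these genes but Abcc2 the most abundant transcript differed between the libraries. The quantifier divides reads shared between transcripts, so each share carries an assignment error that these SDs cover only in part.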

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

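Alternatives named as chosen after the values were seen are spike-in scaling, TPM without the exocrine pancreas and stomach lists, the distal ratio without Fabp1, Lct, Rbp2 and Ada, and the Paneth ratio without Defa genes; all others were planned. Causes were not tested except where the setting's own construction gives them. Over the measures of the whole tissue, 45 of 72 alternatives stayed within a tolerance, 25 went beyond it and 2 reversed the sign. The tolerance was 1.5 times for counts, 1 SD of the replicates for shares and ratios, 0.005 for correlations and 5% for the coefficient of variation, so values within it can still differ clearly, as between single replicates. For shares and ratios, leaving out either replicate moves the mean by less than 1 SD whatever the values. Such an alternative stayed within the tolerance by construction unless the sign reversed, so it shows no stability. With a TPM minimum of 5, 6815 genes were detected, a stricter filter by construction. The correlation was 0.970 with a pseudocount of 0.1, 0.883 over genes with mean TPM of at least 1, 0.946 as Spearman's rho and 0.968 without the pancreas and stomach lists. The coefficient of variation was 0.507 with no filter on low counts, 0.165 as DESeq2's median gene dispersion and 0.392 without the pancreas and stomach lists. Genes over 2-fold apart numbered 3432 from a mean TPM of at least 1 (382 of them higher in replicate 1), 711 with TMM scaling (381 higher in replicate 2, 330 higher in replicate 1), 777 centred on the median gene (464 and 313), 1243 with spike-in scaling (1016 higher in replicate 2) and 1004 without the pancreas and stomach lists (741 higher in replicate 2). The spike-in share was 1.36% on the TPM scale. The log2 ratio of distal to proximal genes was -2.66 as a difference of medians and 1.95 without Fabp1, Lct, Rbp2 and Ada, and ran from -1.65 to 0.49 when either replicate was left out, reversed without replicate 1. The Paneth to goblet ratio was -2.77 without Defa genes, and the major isoform share was 73.2% from a mean TPM of at least 1 and 70.5% with posterior mean TPM. Leaving out either replicate gave 11580 to 12528 detected genes, 43.7% to 67.3% for the 100 most abundant genes, 0.952% to 2.16% for mitochondrial mRNA, 22 to 26 lists with a median at or above 10 TPM, -1.78 to -0.10 for Paneth to goblet and -2.75 to -1.88 for smooth muscle to brush border, and 72.3% to 72.4% for the major isoform share. For single lists, 104 of 111 alternatives kept the call, 4 lost it and 3 gained it (tuft cell and circadian clock over members with mean TPM of at least 5, and B cell with TMM scaling). The median changed sign in 5 alternatives of 3 lists inside the random range, bile acid handling, fasting and fat oxidation, and M cell. Depth limits statements on genes near 3 counts, and counting error stays wide somewhat above that. Nts, with 9 counts in replicate 1, had a credibility interval of 0.089 to 0.338 TPM there.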

Other observations

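All tests in this part were chosen only after the result was seen, except the correction for gene length and GC content, and the antibody, mucin, claudin and other genes given first were chosen after their values were seen. IgA was the most abundant heavy-chain class. Igha held 352843 counts in replicate 1 and 711937 in replicate 2, while Ighm, the IgM constant region, held 3359 and 3485, Ighg2b, an IgG class, 315 and 2887, Ighg1 438 and 1246, and Ighe, of IgE, 0 in both. Of 113 heavy-chain variable genes, 76 had a mean TPM of at least 1. Ighv2-2 took 18.9% of their TPM in replicate 1 and 1.71% in replicate 2, and Ighv1-34 took 6.29% and 22.8%. Of 97 kappa variable genes, Igkv6-23 led in both, with 23.6% and 21.7%. The share of use that the libraries had in common was 44.1% for heavy-chain and 65.4% for kappa genes, with Spearman's rho of 0.764 and 0.842 across genes. Reads of near-identical variable genes are divided by the quantifier, so single genes are uncertain.

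Mucin and claudin genes differed in both directions between the libraries. Muc13 was at 1935 and 1693 TPM and Muc3 at 42.5 and 542 TPM, while the gastric mucin Muc6 was at 381 and 1.13 TPM and Muc1 at 111 and 0.63 TPM. Among claudins, Cldn3 was at 837 and 2005 TPM and Cldn7 at 420 and 1518 TPM, while Cldn18, of stomach epithelium, was at 107 and 0.23 TPM. The pancreatic aquaporin Aqp12 was at 89.6 and 0.12 TPM, and the calcium-binding S100g, induced by vitamin D in the duodenum, was at 143 and 0.48 TPM. Of the small proline-rich Sprr2 genes, Sprr2a2 held 43542 and 28739 TPM and its near copies Sprr2a3 and Sprr2a1 169 and 208 TPM and 49.9 and 63.2 TPM.

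Pancreas and stomach genes were higher in replicate 1. After the median log2 ratio of each length and GC bin was taken out, the exocrine pancreas median was -9.47, against -9.56 before, which argues against such a trend as the whole cause. Pancreas and stomach RNA in the tissue of replicate 1 is a candidate explanation that stays open. All 16 members (100%) lay below -3 log2 units, but this restates the pattern and tests nothing. The islet hormone genes, the other part of this prediction, lay on the same side, with summed values of 100.57 and 2.01 TPM, though Iapp was nearly level. These values go with pancreas RNA in replicate 1 but do not show how it came there. How the tissue was taken is not given in the sources used here. For the faint trace in replicate 2, the median log2 count ratio of stomach minus that of pancreas genes was 0.23; the median gene had 0.160% of its replicate 1 count for pancreas and 0.188% for stomach, and the summed counts 0.337% and 0.264%, raised by Clps, Rnase1 and Pgc. At 0.160%, 4 of the 23 members (Cel, Cela1, Ctrl and Try4) were among 7 that had fewer counts in replicate 2 than carry-over would bring, of 759 genes at a TPM of at least 100 in replicate 1, at a Poisson lower tail of 0.001. These genes lie below carry-over at that rate. As the rate is the pancreas median, some members do so by construction, and lower rates were not tested, so they do not decide against carry-over. The difference of 0.23 and the share of genes below, 0.922%, both stayed under the limits set for carry-over. Those limits were written after the values were seen, so meeting them does not decide for it. Amy2a1, also among the 7, had 82046 counts in replicate 1 and 0 in replicate 2, though reads shared with its paralogs may have been assigned to them. Carry-over of replicate 1 molecules and a little such tissue in replicate 2 both stay open.

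Xist was confined to replicate 1 but for 35 counts, and Y-linked genes to replicate 2. An equal pool of both sexes in each library is argued against by the Y-linked counts, whose upper limit in replicate 1 is 0.315% of those in replicate 2. Too little depth is argued against as well, since replicate 2 had 952 Y-linked counts at nearly equal depth. Xist counts in replicate 2 were 0.465% of those in replicate 1, which restates the pattern, and the 35 counts exceed the 12.05 that carry-over at 0.160% would bring. A candidate explanation that stays open is that each library came from animals of 1 sex, against the label; sex would then be confounded with every other difference between the libraries.

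Some genes under 220 nt were listed at 0 TPM in replicate 1 with reads assigned. Of 81 features with a count above 0 and a TPM of 0 there, only 15 had an effective length of 0, so effective length does not account for all of them; the other 66 have an effective length over 1 nt, where few counts on long features can round to 0.00 TPM. Restricted to genes under 220 nt, a test written after that outcome, 100% had an effective length of 0. The definition of TPM fixes this outcome, so it decides nothing, and no biological explanation was tested.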
